A study of Mus musculus with 6 samples.

How the data were processed

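RNA was measured in mouse common myeloid progenitors, immature blood cells that give rise to granulocytes, monocytes, erythroid cells and megakaryocytes. Per the labels, the cells came from C57Bl/6 mice with a floxed Dot1l gene, which Cre recombinase deletes, and had been transformed with a retrovirus carrying MN1, a leukaemia oncogene, and GFP. They were then transduced with a control vector or with Cre, kept in methylcellulose with IL3, IL6 and SCF, and sorted at day 7. Polyadenylated RNA was sequenced with a stranded kit. There were 3 control and 3 Dot1l-deleted libraries, grouped by the labels. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

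The authors deposited 1 FPKM value (fragments per kilobase of gene, scaled to the mapped fragments of the library) per Ensembl gene and library. Per the submitters' processing notes, CASAVA 1.8.2, GSNAP, SAMtools, Cuffdiff and the mouse build mm9 were used. The notes give no role or order for these tools, and whether strand was used in counting is not given in the sources used here. Each table held 31626 genes, with symbols of that annotation's time. Older symbols are printed as deposited: Evi1 is now Mecom, Mll3 is Kmt2c and Chi3l3 is Chil3. The tables hold no positions, and the annotation used here for lengths and neighbours, GENCODE M21, is on another build, so no coordinates are given.

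A value of 999999999 stood in 304 to 318 genes per library and was read as a failed estimate. The 378 genes that had it in any library were left out, 287 of which had it in all libraries. Some values were vanishingly small, and most mitochondrially encoded genes, which every cell uses, were at exactly 0. A gene at 0 is therefore described as listed at 0. FPKM gives no read counts. The lowest values of small RNA genes, which step by single reads, gave depths of 0.739 to 1.0 relative to the first control library. Between 31 and 48 of 192 to 206 small RNA genes lay at the ratio used, so these depths are approximate.

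The 11924 genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), with no scaling beyond that of the authors. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given as Dot1l-deleted minus control with their standard error (SE). Folds without "log2" are ratios of mean FPKM. Genes with near-identical copies, such as the globins, the Stfa genes, Ly6c1 and Ly6c2, the ribosomal protein genes and the histone genes, can share reads, and their split is uncertain.

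Before the data were examined, 36 gene lists were fixed, along with the tests, the named genes and most of the alternatives. Of 1085 members, counted once per list, 1072 were matched to the files. Lists with at least 5 tested members, 31 in all, were tested against all other genes with camera at a preset correlation between genes of 0.01, with adjustment over the lists. Named genes were Dot1l; Hoxa9, Hoxa10, Meis1, Flt3, Mef2c, Pbx3, Cdk6, Myb and Cdkn1a; the 10 largest changes in each direction among called genes whose groups did not overlap; and up to 4 members of each list with the smallest adjusted p. Predicted genes named Gm or Rik and ribosomal pseudogenes were passed over in the largest changes, which affected 1 gene. A few list members whose deposited symbol differs from the current name of their identifier are counted but not named. The values of some other list members are not reported here.

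Alternatives covered the pseudocount (0.1 and 5), the filter, median-of-ratios, quantile and total scaling, the variance model, sample weights, a block for replicate number, summing of rows with 1 symbol, each library left out, and for lists an estimated correlation and the fry rotation test, which asks whether the genes of a list move on balance one way and compares them with no other genes. Those added after seeing the data were placeholder values taken as missing, median-of-ratios scaling without the third Dot1l-deleted library, the same scaling with the block, and small RNA rows left out.

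The fit was tested on simulated values for 11924 genes with the real means and residual spreads. It called 89.6% of 67 genes changed by a log2 value of 2, 58.2% of 67 changed by 1 and 1.5% of 66 changed by 0.5, and 11 unchanged genes. With no list changed the set test called 0 of 31 lists, and with 1 list raised it called that 1. The simulated genes were independent of each other, so this does not test the preset correlation. Far fewer genes were changed in it than were called in the data, which makes the adjusted threshold stricter. A shift shared by the genes of 1 library was not simulated either. The shares called therefore do not give the power of the real fit. No pair of libraries agreed as closely as a repeated deposit would: over 4877 well-expressed genes the SD of their log2 differences was 0.413 to 0.776, and 2 to 9 values were identical.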

Results

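The data were FPKM values of 3 control and 3 Dot1l-deleted libraries from MN1-transformed mouse myeloid progenitors at day 7. DOT1L is the methyltransferase of lysine 79 on histone H3, and the series title names it as a partner of MN1 in acute myeloid leukaemia. The question was which transcripts change when Dot1l is deleted. The libraries held 17310 to 18034 genes above 0 FPKM.

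Dot1l (ENSMUSG00000061589) was lower in all 3 libraries labelled as deleted. Its FPKM was 20.2, 22.6 and 19.6 in the controls and 8.24, 8.17 and 5.80 after deletion, a 2.81-fold lower mean. The log2 fold change was -1.39 (SE 0.157, adjusted p = 0.000124). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The remaining signal can include reads from outside the deleted part of the gene, which gene-level values do not separate.

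The libraries separated by group. The first principal component held 49.9% of the variance, with the controls between -37.2 and -35.5 and the Dot1l-deleted libraries between 28.8 and 47.8. Pearson correlations across genes were 0.947 to 0.967 within a group and 0.907 to 0.926 between groups.

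The third Dot1l-deleted library stood apart from the other 5. Its tested genes had a median log2 deviation of -0.366 from the 6-library mean, against 0.0499 to 0.103 in the others. One SSU_rRNA_5 row reached 81825 FPKM there, against 485 to 1659 in the others, and the 10 highest rows held 39.0% of the summed FPKM, against 6.59% to 10.8%. With this library included, the median log2 fold change of all tested genes was -0.16. Median-of-ratios scaling brought this to 0.00254, and log2 values on that scale are given as scaled values below.

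**Figure D1:**
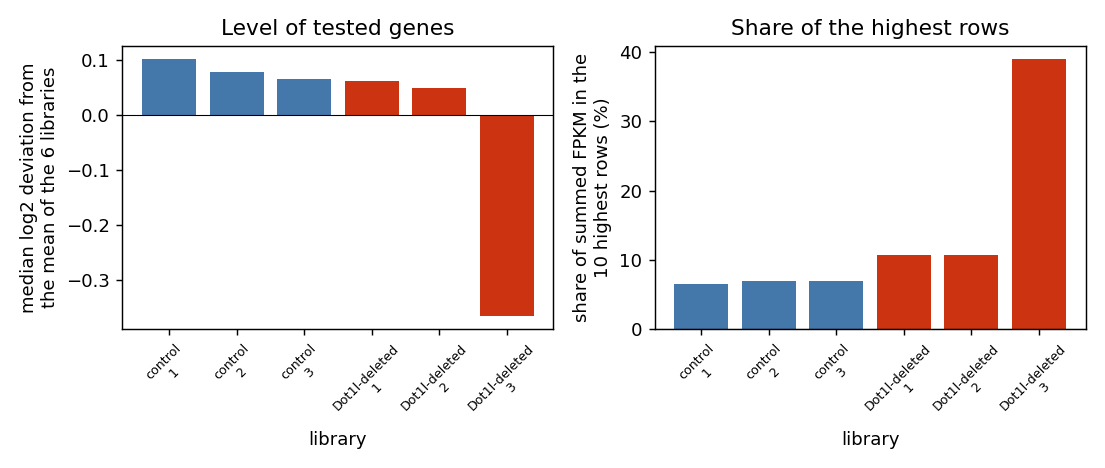
Left, median log2 deviation of the tested genes in each library from the mean of the 6 libraries; right, share of the summed FPKM held by the 10 highest rows of each library, in percent. Blue bars are controls and red bars Dot1l-deleted libraries; the third Dot1l-deleted library lies at -0.366 and 39.0%.

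Between the Dot1l-deleted and the control libraries, 2345 of 11924 tested genes differed, 886 higher after deletion and 1459 lower. No sample had Cre with intact Dot1l, so these differences include any effect of Cre. Of the genes, 907 changed by at least 2-fold, 498 higher and 409 lower. The split depended on the third Dot1l-deleted library and on scaling. Without that library 4558 genes were called, 2041 higher and 2517 lower, and with median-of-ratios scaling 5414 were called, 2754 higher and 2660 lower. The 2-fold totals moved less, to 909 and 888, but their split moved to 573 higher and 336 lower without that library and to 600 and 288 with scaling. Of the 2345 genes, 2304 were also called with scaling and 2291 without that library, all in the same direction.

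On the log2(FPKM + 1) scale the largest rises were those of S100a8 and S100a9, which encode the calprotectin subunits, with log2 fold changes of 4.53 and 4.23. S100a8 went from 567 ± 64.1 to 13073 ± 1305 FPKM (SD, n = 3 each), and S100a9 from 447 ± 52.6 to 8392 ± 775 FPKM. The antimicrobial peptide gene Camp rose from 6.24 ± 1.43 to 110 ± 33.0 FPKM (SD, n = 3 each). Stfa1, Chi3l3, Mgst1 and B4galnt3 rose 14.1-fold to 18.8-fold, and Ly6c2 rose from 40.2 ± 3.19 to 562 ± 117 FPKM. Dgat2 and Mogat2, both acyltransferases of triglyceride synthesis, rose 16.0-fold and 18.5-fold. The log2 fold changes of these 10 genes ran from 3.58 to 4.53, and the adjusted p-values from 1.833e-07 to 7.26e-06.

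On the same scale the largest falls included regulators of blood progenitors. Wt1, a zinc finger transcription factor gene expressed in many leukaemias, fell from 49.2 ± 4.57 to 0.827 ± 0.495 FPKM (SD, n = 3 each). Hlf, a transcription factor gene of haematopoietic stem cells, fell from 116 ± 8.30 to 6.32 ± 1.29 FPKM. Ddx4, a germ cell RNA helicase gene, fell 36.6-fold, the drug efflux pump gene Abcb1a 49.3-fold, the collagen gene Col4a1 27.8-fold, the TNF receptor family gene Cd27 20.4-fold, and Hpgd, which encodes a prostaglandin-degrading enzyme, 24.7-fold. Hpgd varied most, at 4.04 ± 4.15 FPKM after deletion (SD, n = 3). Hoxa9 and Hoxa10 were also among the 10. The tenth was a 5S_rRNA row with 13.7 ± 4.95 FPKM in controls and listed at 0 in the 3 Dot1l-deleted libraries. The adjusted p-values of these genes ran from 1.719e-07 to 5.302e-05.

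Genes of the Hoxa cluster and of the programme known from MLL-rearranged leukaemia fell together. Of 20 tested members, 16 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone. Hoxa9 (ENSMUSG00000038227) fell from 35.9, 40.1 and 39.3 FPKM in the controls to 1.92, 1.07 and 1.51 after deletion, a log2 fold change of -3.99 (SE 0.154, adjusted p = 1.899e-07). Hoxa10 (ENSMUSG00000000938) fell 31.9-fold, Hoxa11 31.5-fold, the receptor tyrosine kinase gene Flt3 16.6-fold and Meis1, whose product binds DNA with HOX proteins, 6.80-fold. The falls were smaller for Cdk6, at a log2 fold change of -1.42 (SE 0.178), Mef2c, at -0.97 (SE 0.165), and Pbx3, at -0.76 (SE 0.142). Myb, an essential progenitor transcription factor gene, was at 257 ± 13.2 FPKM in controls and 263 ± 38.9 after deletion (SD, n = 3 each; log2 fold change 0.02, SE 0.175, adjusted p = 0.939; scaled value 0.21, adjusted p = 0.0531). The mouse Mn1 row was at 49.7, 51.1 and 42.0 FPKM in controls and 69.0, 40.0 and 36.2 after deletion; this gene was not among those fixed beforehand for naming, and whether vector reads enter it is not given in the sources used here. The set test gave an adjusted p of 7.916e-10, and adjusted p = 0.78 with an estimated correlation. The 21 genes of the Hoxb, Hoxc and Hoxd clusters were all below the filter in these cells.

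**Figure D2:**
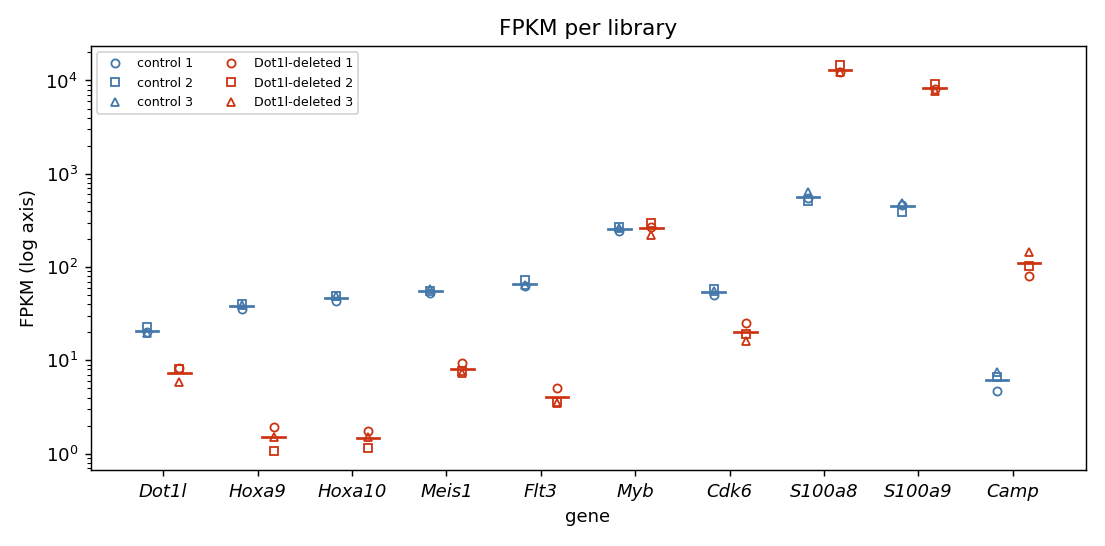
FPKM, on a log axis, of 10 genes in each library; blue symbols are controls, red symbols Dot1l-deleted libraries, the symbol shape gives the replicate number and lines give group means. Hoxa10 went from a mean of 47.2 to 1.48 FPKM and S100a8 from 567 to 13073, while Myb stood at 257 and 263.

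Of 22 tested genes of stem and progenitor cells, 19 fell, 2 rose and 1 did not pass, again with the same counts adjusted over the list alone. Besides Hlf, Cd27, Meis1 and Hoxa9, which the list shares in part with the previous one, it holds Erg, which fell 2.90-fold. The genes that rose were Prom1 and Ly6a, with log2 fold changes of 1.99 and 0.72. Prom1 and Ly6a, like other genes named outside the rule, were chosen after their values were seen. The set test gave an adjusted p of 1.815e-11, and adjusted p = 0.78 with an estimated correlation.

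Granule and neutrophil genes rose. Of 15 genes of primary granules and early neutrophils, 10 rose and none fell; adjusted over the list alone, 11 rose and 1 fell, and 11 rose and 2 fell with median-of-ratios scaling as well as without the third Dot1l-deleted library. Prtn3, encoding proteinase 3, rose from 148 ± 20.3 to 1181 ± 278 FPKM (SD, n = 3 each), and Cebpe, a transcription factor gene of granulocyte maturation, rose 6.63-fold. Clec5a rose 11.8-fold, and Igsf6 by a log2 fold change of 3.28 (SE 0.153). Of 23 genes of late neutrophils, 22 rose and none fell; adjusted over the list alone, 22 rose and 1 fell. Beyond S100a8 and S100a9, Fcnb, encoding ficolin B, went from 0.199 ± 0.0585 to 8.08 ± 0.421 FPKM. The set tests gave adjusted p-values of 1.86e-10 and 1.578e-31. With an estimated correlation they gave adjusted p = 0.78 for the early list and adjusted p = 0.0718 for the late one.

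Of 29 tested genes of monocytes and macrophages, 21 rose, 2 fell and 6 did not pass; adjusted over the list alone, 23 rose and 3 fell. Lyz2, the lysozyme gene of myeloid cells, rose from 53.4 ± 10.7 to 383 ± 25.8 FPKM (SD, n = 3 each), and the chemokine gene Ccl6 rose 7.47-fold. The genes that fell, Ccr2 and Cd163, had log2 fold changes of -0.84 and -0.86. The set test gave an adjusted p of 5.048e-19, and adjusted p = 0.78 with an estimated correlation.

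Of 34 interferon-stimulated genes, 17 rose, 1 fell and 16 did not pass; adjusted over the list alone, 20 rose and 1 fell. The chemokine gene Cxcl10 rose 13.4-fold, Isg15 5.16-fold and Dhx58 3.13-fold, while the interferon-gamma-induced GTPase gene Ifi47 fell 2.42-fold. The number that rose was 29 without the third Dot1l-deleted library and 31 with median-of-ratios scaling. The set test gave an adjusted p of 4.016e-15, adjusted p = 0.802 with an estimated correlation and adjusted p = 0.0601 with fry.

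Of 26 mast cell and basophil genes, 6 rose and 10 fell; adjusted over the list alone, 8 rose and 12 fell. Ms4a2, the beta chain gene of the IgE receptor, fell 3.73-fold and Il6 2.69-fold, while the protease gene Mcpt2 rose 8.28-fold. Of 18 erythroid genes, 7 rose and 7 fell, with the same counts adjusted over the list alone. Most erythroid genes below the filter, untested, were higher in every Dot1l-deleted library than in any control, and Epb4.2 was not. Rhag was at 2.09, 1.76 and 1.68 FPKM after deletion, against 0.153, 0.197 and 0.0776 in controls. The globin genes Hbb-b2 and Hba-a1 rose to 20.1 ± 4.16 and 7.94 ± 1.23 FPKM from 1.98 ± 0.0358 and 0.569 ± 0.348 (SD, n = 3 each). Globin genes can share reads with their near-identical copies, so these rows do not give the change of total globin RNA. Aqp1 rose 12.5-fold, while Gfi1b, a transcription factor gene of erythroid and megakaryocyte development, fell 3.61-fold. Of 17 megakaryocyte genes, 3 rose and 8 fell; adjusted over the list alone, 4 rose and 9 fell. Itga2b, the CD41 gene, fell 4.43-fold and the thrombin receptor gene F2r 2.39-fold, while the genes that rose were Thbs1, at 3.38-fold, Ppbp, at 13.9-fold, and Pf4, at 1.73-fold. All 4 tested eosinophil genes rose, over all genes and adjusted over the list alone, among them Prg2 at 10.2-fold, S100a6 at 2.20-fold and Cebpe. Of 12 dendritic cell and MHC class II genes, 4 rose and 5 fell, with the same counts adjusted over the list alone; H2-DMa fell 4.56-fold and H2-Ob 3.74-fold, with Tcf4 and Ly6d also lower, Cd74, Mgl1 and Id2 rose, and Cd80 rose from 0.243 ± 0.102 to 2.65 ± 0.482 FPKM. With median-of-ratios scaling, 5 megakaryocyte genes rose and 9 fell, and 6 dendritic cell genes rose and 5 fell. The set tests of the mast cell, erythroid, megakaryocyte and dendritic lists gave adjusted p-values of 0.818, 0.136, 0.416 and 0.821. The erythroid list passed, in the upward direction, without control replicate 1, 2 or 3, at 0.00789, 0.00826 and 0.00732, and without the second Dot1l-deleted library, at 0.0356.

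Few markers of other cell types were measurable. Of 3 tested B cell genes, Cd79b rose 3.68-fold and Rag2 fell 4.16-fold. Of 5 T and NK cell genes, Thy1 fell 4.85-fold and Cd28 4.14-fold, and none rose. Of 7 fibroblast, stromal and endothelial genes, Acta2 and Fbn1 rose 7.40-fold and 1.62-fold, and Thy1 and Pecam1 fell. Fbn1 and Pecam1 lost the call without each control library in turn and without Dot1l-deleted replicate 2, Fbn1 also without Dot1l-deleted replicate 1 and with scaling to the total, and Pecam1 with no filter. In these 3 lists the counts adjusted over the list alone were the same. The T and NK list gave an adjusted p of 0.0944 and the stromal list 0.540.

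Cytokine receptor and transcription factor genes changed in both directions. Of 33 cytokine receptor and signal feedback genes, 6 rose and 13 fell; adjusted over the list alone, 6 rose and 17 fell. The interferon-gamma receptor gene Ifngr1 rose 4.38-fold and the GM-CSF receptor gene Csf2ra 3.31-fold, while the interleukin 10 receptor gene Il10ra fell 4.01-fold. Of 38 myeloid transcription factor genes, 6 rose and 13 fell; adjusted over the list alone, 9 rose and 17 fell. With median-of-ratios scaling 10 receptor and feedback genes rose and 16 fell, and 13 transcription factor genes rose and 17 fell, against 12 and 17 without the third Dot1l-deleted library. Erg fell 2.90-fold and Egr1, an early response gene, 12.8-fold. Of 20 immediate early and heat shock genes, 6 fell and none rose, and 8 fell adjusted over the list alone; with median-of-ratios scaling 2 rose and 7 fell. Ier3 fell 2.51-fold, Dusp1 2.57-fold and Dusp2 2.29-fold. The set tests gave adjusted p-values of 0.473, 0.833 and 0.0421; the last became adjusted p = 0.965 with an estimated correlation and 0.133 with median-of-ratios scaling, 0.0781 without the second Dot1l-deleted library and 0.0720 without the third. Of 21 inflammatory cytokine and NF-kB target genes, 2 rose and 5 fell, and 3 rose and 7 fell adjusted over the list alone. Il1rn rose 3.62-fold and Cxcl3 7.52-fold, Il1a fell 2.30-fold, and Il6, Nfkbiz, Ccl7 and Ccl2 were the others that fell. With median-of-ratios scaling 8 rose and 7 fell, and 5 rose and 4 fell without the third Dot1l-deleted library, and the set test gave an adjusted p of 0.603.

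Of 17 genes of the DOT1L complex and elongation factors, Mllt3 and Mllt6 fell, by 2.16 and 0.51 on the log2 scale, with the same counts adjusted over the list alone. Of 15 MLL complex genes, Psip1 and Mll3 fell, and none passed adjusted over the list alone. Of 40 mitosis genes, only Mad2l1 fell, and of 47 DNA replication genes, Tyms, Chaf1b and Pole fell; none of either list passed adjusted over the list alone. With median-of-ratios scaling, 9 mitosis genes were called higher and 7 lower, and 9 and 14 of the DNA replication genes. In the mitosis list 2 rose and 9 fell without the third Dot1l-deleted library, and in the DNA replication list 3 and 11. In the DOT1L complex list 1 rose and 5 fell with that scaling and 1 and 6 without that library, and in the MLL complex list 2 rose and 3 fell in both. Cdkn2c and Cdkn2b fell among 6 cyclin-dependent kinase inhibitor genes, with the same counts adjusted over the list alone; Cdkn2b lost the call with median-of-ratios scaling (adjusted p = 0.0856) and without control replicate 1, control replicate 3 or Dot1l-deleted replicate 1. Cdkn1a was at 99.8 ± 10.1 FPKM in controls and 89.0 ± 14.2 after deletion (SD, n = 3 each; adjusted p = 0.538). Of 33 p53 target genes, Fas rose 2.39-fold and 7 fell, among them Sesn1, Zmat3 and Abhd4; adjusted over the list alone, 3 rose and 9 fell, and with median-of-ratios scaling 6 rose and 10 fell, against 6 and 8 without the third Dot1l-deleted library. Of 12 BCL2 family genes, Bcl2 alone passed with the values as deposited and fell 3.54-fold, also adjusted over the list alone; with median-of-ratios scaling 4 rose and 2 fell, and 1 rose and 1 fell without the third Dot1l-deleted library. Without each control library in turn, Mllt6, Psip1, Mll3, Mad2l1, Tyms, Chaf1b and Pole lost the call, the first 3 also without Dot1l-deleted replicate 2; with no filter Mllt6, Mll3, Pole and Cdkn2b lost it, and Mll3 and Pole without the variance trend. The set tests of these 7 lists gave adjusted p-values of 0.257 to 0.833.

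No gene passed among 43 MYC target and ribosome biogenesis genes or 53 oxidative phosphorylation genes, over all genes by limma or adjusted over the list alone. At an unadjusted p under 0.05, limma gave 4 genes in the first list and 2 in the second. With median-of-ratios scaling, 2 rose and 8 fell in the first list and 4 rose and 5 fell in the second, and with quantile normalization 2 rose and 15 fell in the first and 3 rose and 21 fell in the second. The counts were 1 and 4, and 3 and 4, without the third Dot1l-deleted library. Of 75 ribosomal protein genes, Rps28 fell 1.79-fold, a call lost with no filter, and none passed adjusted over the list alone. With quantile normalization 1 rose and 22 fell, or 1 and 18 adjusted over the list alone, with median-of-ratios scaling 3 rose and 2 fell, and without that library 2 and 2. Of 22 glycolysis genes, 2 rose and 5 fell, and 2 rose and 6 fell adjusted over the list alone; the hexokinase gene Hk3 rose 4.58-fold and Ldhb 5.75-fold, while the glucose transporter gene Slc2a3 fell 2.09-fold, and Eno2, Pfkm, Pdk1 and Hk1 also fell. With median-of-ratios scaling 4 rose and 9 fell. Of 24 cholesterol synthesis genes, 1 rose, with the same count adjusted over the list alone, while 7 rose and 3 fell with median-of-ratios scaling, and 5 rose and 1 fell without that library. Of 31 amino acid and unfolded protein response genes, Slc7a11 rose and Trib3, Herpud1 and Ddit3 fell; adjusted over the list alone, 1 fell. Herpud1, Ddit3 and Slc7a11 lost the call without each control library in turn and with no filter, Slc7a11 also without Dot1l-deleted replicate 1 or 2 and with scaling to the total, and Ddit3 without the variance trend. With median-of-ratios scaling 7 rose and 10 fell, and without that library 5 rose and 10 fell. Of 23 long genes, 2 rose and 5 fell, and 2 rose and 8 fell adjusted over the list alone, with Foxp1 down 2.79-fold and Rere 2.67-fold, Vps13a, Lrba and Utrn also lower, and Syne1 and Syne2 higher; 3 rose and 10 fell with median-of-ratios scaling, and 3 and 8 without that library. The set tests of these lists gave adjusted p-values of 0.241 to 0.526.

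**Figure D3:**
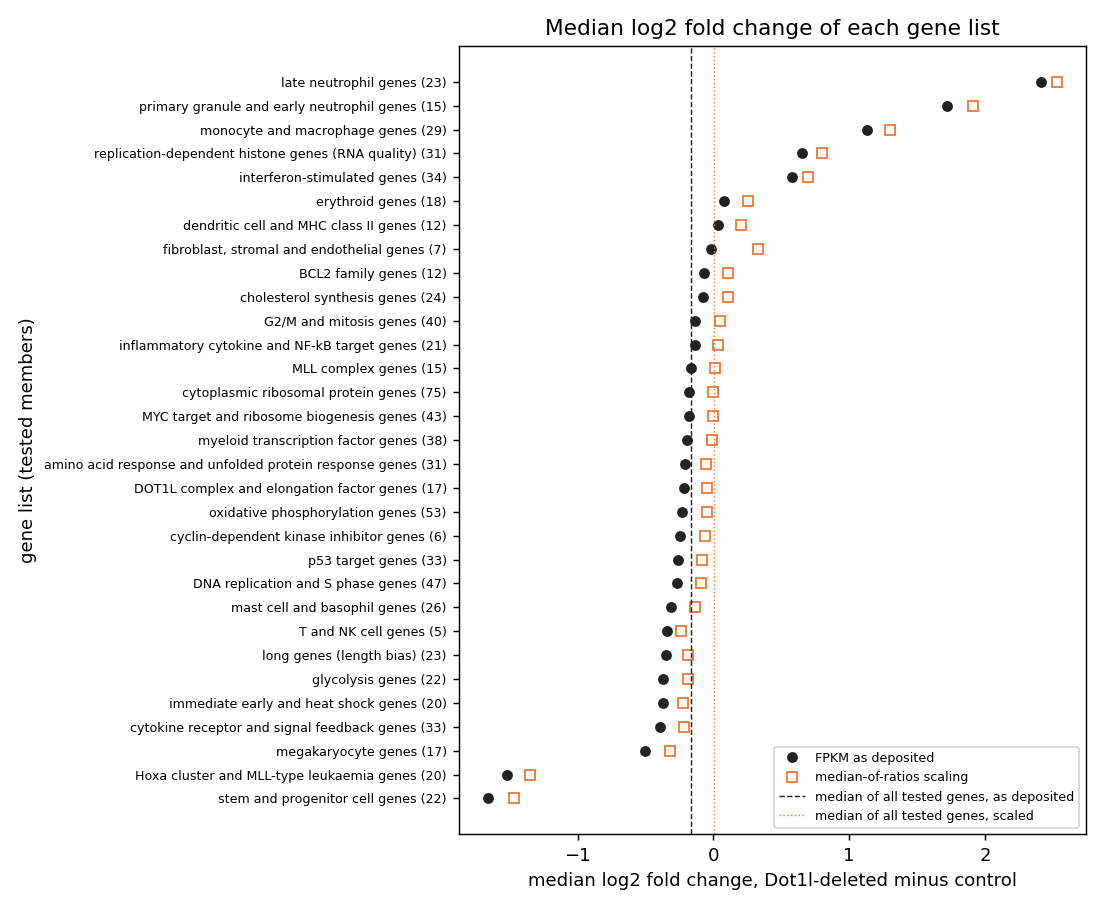
Median log2 fold change, Dot1l-deleted minus control, of the 31 gene lists with at least 5 tested members, with the number tested in brackets; filled circles are FPKM as deposited, open squares median-of-ratios scaling, and vertical lines the medians of all tested genes. The late neutrophil list lies highest, at 2.41 as deposited, and the stem and progenitor list lowest, at -1.66.

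Among the lists for RNA quality, 28 of 31 tested replication-dependent histone genes had their highest value in the third Dot1l-deleted library, which also brought many of them past the filter; of the 14 with a mean FPKM of at least 1 over the other 5 libraries, 11 did. By limma none rose and Hist1h2bc fell, with 3 at an unadjusted p under 0.05, and none passed adjusted over the list alone; without that library 4 of 14 fell. With median-of-ratios scaling Hist1h2bc lost the call (adjusted p = 0.188), as it did with quantile normalization, without each control library in turn, without Dot1l-deleted replicate 2, with no filter, with the filter at 5 FPKM and without the variance trend. The set test gave an adjusted p of 0.00295 upward, adjusted p = 0.965 with an estimated correlation and 0.218 downward without that library. The 1 tested mitochondrially encoded gene, mt-Atp6, was at 188, 198 and 178 FPKM in controls and 95.7, 263 and 189 after deletion, and no sex-linked gene passed the filter.

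In all, 8 of the 31 lists passed the set test, and with an estimated correlation camera passed 0, with 1 at an unadjusted p under 0.05. The correlations were estimated only on values as deposited, with the third Dot1l-deleted library included. They were high also in lists with few calls, at 0.905 for mitosis and 0.934 for DNA replication genes. An offset shared by most genes of a library by itself makes their deviations from the group mean correlate. Whether it raised these estimates was not tested, so the 0 lists that passed cannot tell whether a list moves apart from other genes. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 7. In the stromal, BCL2, cholesterol and inflammatory lists the median was below 0 while the set test, which compares a list with all other genes, pointed upward. Other splits of the 6 libraries into 3 and 3 passed 5 to 14 lists. Each of them keeps part of the genotype difference between its sides, so these counts cannot tell whether the number that passed is specific to genotype.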

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

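Tests of the explanations below were chosen only after the result was seen, except those of other splits of the libraries, of transcript length and of interferon genes. The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The split by group gave 2345 changed genes against at most 9 in another split, and 907 genes changed by at least 2-fold against at most 9, so 1 of the 10 splits reached each of these. Every other split mixes the groups, so the genotype difference adds to its spread, which by itself lowers the number of genes called. Part of that difference also stays between its sides. For the gene lists, 6 of the 10 splits gave 8 lists or more. The highest, 14, came from setting control replicate 1 with Dot1l-deleted replicates 2 and 3. The cause of that count was not tested.

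Genes with a failed estimate in some libraries were outside the main comparison. Of these, 63 had at least 2 values in each group and a mean FPKM of at least 1, and 7 of them changed, 2 higher and 5 lower, by limma on the values present. Lmna rose from 4.96 ± 0.171 (SD, n = 3) to 12.2 ± 2.65 FPKM (SD, n = 2; adjusted p = 0.00125), and Robo1 fell from 2.22 ± 0.0304 (SD, n = 3) to 0.327 ± 0.00779 FPKM (SD, n = 2; adjusted p = 0.00198). Both were chosen after their values were seen.

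The third Dot1l-deleted library lay below the others in most genes. Loss that grows with transcript length would have given a negative rank correlation between length and the difference from the other Dot1l-deleted libraries; Spearman's rho across genes, which are not independent replicates, was 0.159. Relative depth was 0.873, inside the 0.739 to 1 of the others. It follows the scaling to mapped fragments that FPKM already has, so it cannot tell whether fewer fragments came from messenger RNA. Lower depth was therefore not decided. A larger share of RNA without a poly(A) tail stays open as an explanation of the low values. The SSU_rRNA_5 row, of ribosomal RNA, goes with it, at 13.1% of the summed FPKM here. Histone transcripts mostly lack that tail. Of 14 histone genes with a mean of at least 1 FPKM over the other 5 libraries, 11 peaked in this library. That is just under the 80% set for this explanation, but this choice favours histone transcripts that poly(A) selection keeps. Of 50 histone genes above 0 FPKM in any library, 45 peaked here, but that choice uses this library. No biological explanation was tested.

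The Hoxa, MLL-type and stem cell genes called lower were 32 genes over both lists. Replacement of the progenitors by cells lacking all these genes would lower them by about 1 factor. Of the 26 with a control mean of at least 10 FPKM, however, 13 had 95% intervals wholly above a log2 change of -2, while Hoxa10 was at -4.29. The bound of 10 FPKM was set after a first run. Replacement by cells that keep some of these transcripts could give unequal falls and was not tested. Scaling is argued against as the whole cause, since 32 stayed lower under each of 3 scalings. Cre itself and loss of Dot1l cannot be told apart, because no sample had Cre with intact Dot1l. As values only, 1 of 33 p53 target genes was called higher and 7 lower. With median-of-ratios scaling 6 were higher and 10 lower, and without the third Dot1l-deleted library 6 and 8. A shift of the cells toward maturation stays open and untested.

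The interferon-stimulated genes called higher were 17. All 17 were also called higher without the third Dot1l-deleted library, so the calls do not rest on it. This was a weak test, since among the Dot1l-deleted libraries that one had the lowest Cxcl10, Isg15 and Dhx58 values. Macrophages carried into the sort were looked for with 7 marker genes. The highest value of these in a Dot1l-deleted library was 0.0889 FPKM, for C1qb, although markers listed at 0 can be failed estimates. Macrophages that do not express these markers would be missed, so macrophages in the sort are not excluded. Mrc1, an untested macrophage list member, was at 2.06, 1.67 and 1.19 FPKM after deletion and 0.284, 0.349 and 0.185 in controls. Cx3cr1, another, did not rise, at 0.693, 0.743 and 0.492 FPKM after deletion and 0.841, 1.29 and 0.732 in controls. Both were chosen after their values were seen. Of 19 interferon genes the highest mean after deletion was 0.043 FPKM, for Ifnk, which decides nothing, since interferon could act after its transcript is gone or come from outside the cells. Of 29 monocyte and macrophage genes 21 were higher and 2 lower, with a set test at adjusted p = 0.78 with an estimated correlation, and a link between the lists was not tested.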

How the results depend on the processing

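Alternatives called added, and all they gave, were chosen after seeing the data; the others were fixed before. Dot1l stayed lower and past the threshold in every alternative, with log2 fold changes from -1.58 to -1.06 and adjusted p-values from 1.128e-14 to 0.00338. Of 112 named genes other than Dot1l, none turned direction with a call. The most that lost the call were 14, without control replicate 1 or control replicate 3. Such fits have fewer samples. Without Dot1l-deleted replicate 3, which leaves as few samples, 0 lost the call and 4 gained it. Fewer samples alone therefore do not account for the losses. With the filter at 5 FPKM only 89 of the 112 were tested, and 1 of them lost the call. Mll3 and Cdkn2b lost it with both added alternatives that use median-of-ratios scaling, and Hist1h2bc with the blocked one of them.

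The count of changed genes was 2345. It was 5414 with median-of-ratios scaling (2754 higher, 2660 lower), 5608 with quantile normalization (2412 and 3196), 5716 with sample weights (2531 and 3185), 4556 with added median-of-ratios scaling without the third Dot1l-deleted library (2319 and 2237) and 4470 with that scaling and a replicate block, also added (2314 higher). Sample weights gave that library 0.0497, against 0.945 to 3.455 for the others. Leaving out 1 library gave 1819 to 4558 changed genes, 700 to 2041 higher and 1012 to 2517 lower, with the highest counts without the third Dot1l-deleted library. With no filter, 1342 were higher. The 2-fold counts fell to 433 (244 higher, 189 lower) with a pseudocount of 5, which shrinks the change of low genes by construction. With the filter at 5 FPKM 322 were higher by at least 2-fold, with fewer genes tested, and with scaling to the total 692 were lower by at least 2-fold.

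A replicate block gave 2953 changed genes, 1152 higher and 1801 lower. Deviations of same-numbered libraries correlated at -0.0301, -0.0377 and 0.0128 across genes, and not every library correlated best with its own number. These values give no sign that the numbers pair the samples. They cannot exclude a pairing with a small effect, and the labels do not say. The block moved the erythroid list to adjusted p = 0.0333 and no other set test call. Of the histone genes the block called 16 higher and 1 lower, or 20 and 2 adjusted over the list alone. Without it the counts were 0 and 1, or 0 and 0. Of these 31 genes 28 peaked in the third Dot1l-deleted library. Without that library, and with no block, 0 of 14 rose and 4 fell. The cause of the added calls was not tested.

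Of the 31 lists, 8 passed, against 0 with a correlation estimated without scaling and with the third Dot1l-deleted library included. With no filter 34 lists had enough tested members and 13 passed, 12 of the 31 and the eosinophil list (8.434e-08). The estimated correlation gave adjusted p = 0.780 for the Hoxa, stem, early neutrophil and monocyte lists, 0.0718 for late neutrophil, 0.802 for interferon and 0.965 for immediate early and histone genes. In the other 23 alternatives, fry among them, the first 5 of these stayed past the threshold, the highest adjusted p being 0.00638. The fry test asks whether a list moves on balance one way, not whether it differs from other genes, so its p-values bear on another question; it gave 0.0601 for interferon, which passed in the other 22. With no filter, the DOT1L complex (0.0193), erythroid (1.5e-05), DNA replication (0.0129), MYC (0.0319) and oxidative phosphorylation (0.0209) lists passed. The last also passed with quantile normalization (0.0191), and the mast cell list with the filter at 5 FPKM (0.0141). For the T and NK list fry gave 0.00995. The erythroid list also passed with scaling to the total (9.447e-05) and with small RNA rows left out, an added alternative (0.0205), and ranged from 0.00732 to 0.596 with 1 library left out.

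The immediate early list, at 0.0421, gave 0.0551 with a pseudocount of 0.1, 0.0690 with no filter, 0.133 with median-of-ratios scaling, 0.0629 with quantile normalization, 0.119 with scaling to the total, 0.05002 with sample weights, 0.0582 with added scaling without the third Dot1l-deleted library, 0.152 with added scaling and block, and 0.0164 to 0.0781 with 1 library left out. The histone list, at 0.00295, gave 0.449 with median-of-ratios scaling, 0.265 with quantile normalization, 0.329 with scaling and block, and 0.638 with fry. It turned downward with sample weights (0.416), without the third Dot1l-deleted library (0.218) and with added scaling without it (0.157), and ranged from 3.333e-09 to 0.218 with 1 library left out. Where no reason is given, the cause was not tested. Read depth behind single values is unknown.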

Other observations

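A scan chosen after the data were seen grouped tested genes by the letters that start their symbols and ran the set test on the 153 groups with at least 8 members. The Clec genes, which encode C-type lectins, had 7 of 14 members higher and none lower (median log2 fold change 0.69, adjusted p = 4.45e-06), and the Cyp genes of the cytochrome P450 family had 8 of 14 higher and 1 lower (median 0.65, adjusted p = 2.86e-05). Both gave adjusted p = 0.997 with an estimated correlation and 0.0583, still upward, with median-of-ratios scaling. No other group passed.

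It was hypothesised, before the result was seen, that neighbouring genes change together. Among 10876 pairs of neighbouring tested genes with differently named members, 72 pairs had both genes changed by at least 2-fold in the same direction, against a mean of 32 in 10000 shuffles of the genes. The permutation p was 1e-04, the smallest the shuffles can give. Leaving out pairs that overlap, chosen afterwards, left 67 pairs against 28.3. Shared regulation may contribute, but related genes with unlike names and other features shared by neighbours were not separated.

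It was also hypothesised beforehand that long genes fall more than short ones. Spearman's rho across 11382 genes between gene length and log2 fold change was -0.13 as deposited, -0.127 with median-of-ratios scaling and -0.125 without the third Dot1l-deleted library. The sign fits the hypothesis, the relation is weak, and genes are not independent replicates. Length was not separated from other properties of the genes.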
